A study of Drosophila melanogaster with 2 samples.

How the data were processed

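The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) of tx, also called taxi or delilah, a basic helix-loop-helix (bHLH) transcription factor of Drosophila tendon cells and of the wing. Per the labels, the flies carried tx fused to green fluorescent protein, the antibody was directed against that tag, and chromatin from whole embryos of both sexes, aged 0 to 24 h, was sonicated to fragments of 200 to 800 bp. There were 2 biological replicates of this 1 group. No control-group samples were analysed here. Both replicates' peaks were called against 1 shared control, per the text accompanying the deposited files, so part of any overlap between the replicates may come from that control. The aligner and the peak caller are not given in the sources used here, and the read depth is unknown.

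The authors deposited peak lists on the dm6 and dm3 genome builds. For each build there were relaxed lists of 30000 peaks for replicate 1, for replicate 2 and for the pooled replicates, and 1 optimal set chosen by the irreproducible discovery rate (IDR). The deposited signal value of each peak is the authors' own, is never negative and was used to rank or describe peaks within a list and, as log signal, to correlate the replicates. The deposited q-value column is in −log10 units by the file format, the base being taken from that format. It is capped (all 3102 dm6 optimal IDR peaks share the value 4.02) and was not used for ranking. Most peaks of a list have 1 width (median 420 bp in replicate 1, 376 bp in replicate 2 and 410 bp in the pooled list). The dm6 optimal IDR peaks were the same intervals and signals as the top 3102 of the pooled relaxed list, and the dm3 set of 2997 peaks likewise.

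Genes came from the Ensembl release 115 annotation (BDGP6.54) and sequence from the Release 6 genome, whose arm lengths match dm6. dm3 coordinates were counted and never converted. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Transcription start sites (TSSs) were those of protein-coding transcripts, a choice made after the peak lists had been opened. Each summit was assigned to the first class that applied: within 1000 bp of a TSS, 5′ UTR, 3′ UTR, coding exon, other exon, intron or intergenic. Class shares were compared with 1000 random placements on the same arms outside assembly gaps by a two-sided permutation test. Peaks per arm were compared with the non-gap length by a two-sided exact binomial test. A gene was called bound when an optimal IDR summit lay within 1000 bp of any of its TSSs, and 19 gene lists fixed before the data were examined were compared with all other protein-coding genes of 6 arms by a two-sided Fisher's exact test. Odds ratios carry 0.5 added to each cell. Of 301 list entries 296 matched a gene, 8 of them through a synonym and 2 through a full name, which were looked up after the annotation was opened.

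Motifs were searched on both strands in windows of 50 bp either side of each summit and in windows of the same width centred 500 bp to the left and right. The summit share is set against the mean of both flanks, and the two-sided exact McNemar test uses a seeded random choice of 1 flank per peak. All 10 CANNTG classes and any CANNTG, 7 other motifs, and 2080 6-mers were each adjusted within their family by the Benjamini-Hochberg method, as were regions, arms and lists. A result was called at an adjusted p below 0.05. Replicates were compared by the share of their top 3102 peaks with summits within 100 bp, against 1000 random placements (100 for the rules on interval overlap), and by Spearman and Pearson correlation of log signal across peaks, with no p because peaks are not replicates. Intervals are 95% Wilson intervals for shares and exact Poisson intervals for peaks per Mb. They cover counting of peaks or genes only.

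Genes named by rule are those with the TSS nearest to the 20 strongest optimal IDR peaks, the 10 protein-coding genes with the most summits in the gene body plus 1000 bp (with ties at the last place kept), up to 4 bound members of each list with the strongest promoter peak, and tx. The scripts were tested on simulated data. Random summits gave 0 of 7 regions, 0 of 11 E-box tests and 0 of 2080 6-mers called, and a CAGCTG planted in 10% of windows ranked 1 among 6-mers. Random positions have no built-in GC difference from their flanks, whereas the optimal IDR summits had one (36.2% against 44.0%). The simulation therefore does not cover motif calls against flanks under such a difference. Of 100 simulated lists of 16 genes with 60% bound members expected, 90 were called, and 1 of 100 random lists was.

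Alternatives fixed before the data were examined took the 1551 strongest peaks, each replicate alone, other TSS distances, other assignments of peaks to genes, lists matched on gene structure, and other motif windows and controls. For matching, genes were put in length quintiles crossed with 4 classes of TSS number, or in length deciles, and 10000 lists were drawn. Added after the data were seen were the arms without Y, the motif alternatives for the other motifs and 6-mers, lower-ranked peaks, gene families by symbol and core promoter motifs. A few named items covered by these rules are not reported here.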

Results

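Binding of the tagged tx protein was recorded as peaks from whole embryos in 2 biological replicates. The optimal IDR set held 3102 peaks on dm6, covering 1098 kb, with a median authors' signal of 91.2 and a maximum of 1473. Each relaxed list held 30000 peaks, and the median signal was 15.3 in replicate 1 and 8.54 in replicate 2. Read depth is unknown, so signals of different lists were compared only by rank or correlation, never by size.

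The first comparison asked how far the replicates located the same sites. The strongest peaks were shared: the peak near CG14100 ranked 2 in replicate 1 and 1 in replicate 2, and the peak in the intron near cbt, which encodes the zinc finger factor cabut, ranked 1 and 2. Of the top 3102 peaks of replicate 1, 2013 (64.9%, 95% Wilson interval 63.2 to 66.6%) had a top 3102 summit of replicate 2 within 100 bp, against 0.462% for random placements (SD 0.124). The permutation p was 0.001, the smallest that 1000 placements can give. Placements were uniform along each arm, whereas 65.0% of the top 3102 of replicate 1 and 62.2% of those of replicate 2 lay at promoters. A shared preference for promoters alone would exceed this random level, so the p does not test agreement beyond it. The share was 71.3% for the top 1551 peaks and 51.4% for the top 6204. Of the optimal IDR peaks, 3049 had a summit in the relaxed list of replicate 1 and 2871 in that of replicate 2, whatever its q-value there. Across the 2822 peaks found in both, log signals correlated with Spearman's rho 0.643 and Pearson's r 0.726, and peaks are not independent replicates. Part of the overlap may come from the shared control.

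The second comparison asked which parts of the genome carried the peaks. No immunoprecipitate without the tagged protein was analysed here, so peaks may include signal that does not come from tx. Promoters held 2014 of 3102 summits (64.9%, interval 63.2 to 66.6%), against 20.4% of random placements, a 3.19-fold excess. Introns held 726 summits (23.4% against 36.9%) and intergenic DNA 283 (9.12% against 26.2%). Coding exons held 7 summits (0.226% against 10.2%, and 0.613% with replicate 2 alone), and 3′ UTRs 19 (0.613% against 4.40%). Each of these 5 classes had an adjusted permutation p of 0.0014. The 5′ UTR outside promoters held 4 summits, a ratio of 0.278 with adjusted permutation p = 0.00932, and other exons did not differ (49 summits, adjusted p = 0.494). Promoter summits lay at a median of 121 bp from the nearest TSS, and 78.2% of them were upstream of it. The 5′ UTR call was lost with a TSS distance of 500 bp (adjusted permutation p = 0.0979) or 2000 bp (adjusted p = 0.0816).

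**Figure D1:**
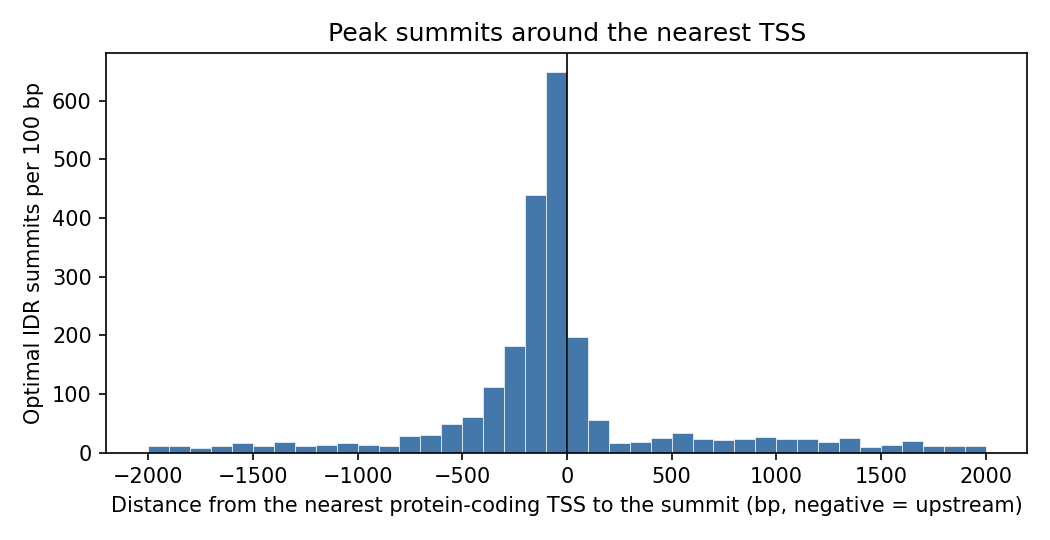
Number of optimal IDR summits per 100 bp (vertical axis) by distance to the nearest protein-coding TSS in bp (horizontal axis, negative values upstream). The summits pile up just upstream of the TSS, with a median of 121 bp from it among promoter summits.

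**Figure D2:**
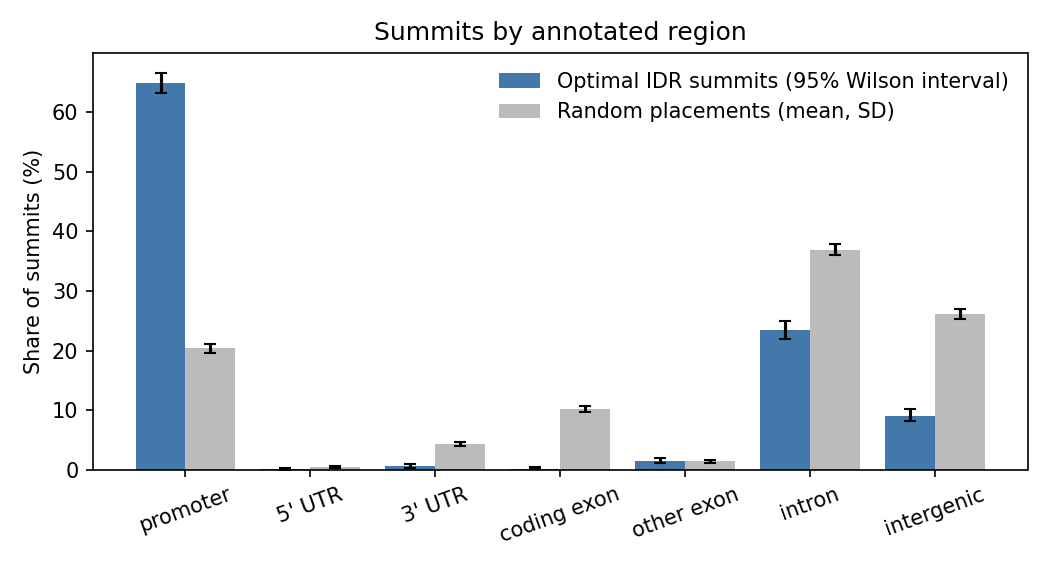
Share of the 3102 optimal IDR summits in each annotated region (blue, bars to the 95% Wilson interval) and of random placements on the same arms (grey, mean and SD of 1000 placements). Promoters stand at 64.9% against 20.4%, and every called other region lies below its random share.

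Among chromosome arms, the small heterochromatic chromosome 4 carried few peaks. It held 12 peaks, or 9.01 per Mb (exact Poisson interval 4.66 to 15.7), 0.398 times the number its length predicts (exact binomial test, adjusted p = 0.00111). Arm 2L held 585 peaks, 24.9 per Mb, 1.10 times the predicted number (adjusted exact p = 0.0309). The X, present in 1 copy in males and therefore at lower dose in mixed-sex embryos, held 561 peaks, 23.9 per Mb, and did not pass (adjusted exact p = 0.224), though with replicate 2 alone it did (ratio 1.12, adjusted p = 0.0109). Y held 0 peaks (adjusted exact p = 1.5e-33), which allows up to 1.08 per Mb, but none of the dm6 lists holds a peak there, so its absence may be set upstream. Without Y the 2L call was lost (ratio 1.07, adjusted exact p = 0.132), and among the 1551 strongest peaks those of 2L (adjusted p = 0.224) and of chromosome 4 (ratio 0.597, adjusted p = 0.35) were lost.

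The strongest peaks lay mostly at promoters. On dm6 the first, at chromosome 3L from 19590399 to 19590820, had a signal of 1473 and its summit 90 bp from the TSS of CG14100. The second, on 2L from 480861 to 481339 (signal 1421), lay in an intron, 1376 bp from the TSS of cbt and inside ush, which encodes a cofactor of GATA factors. The third, on X from 2703674 to 2704106, lay 42 bp from the TSS of Ugalt, a transporter of UDP-galactose, and within 1000 bp of that of eIF2Bbeta, a translation initiation factor subunit. Next came promoter peaks at px, the wing vein gene plexus (signal 1008), at Chro, the chromatin protein Chromator (999.8), and at Lk6, a kinase of the translation factor eIF4E (968.5). Others of the 20 were at promoters of genes of the mitochondrial ribosome and RNA metabolism, mRpL41 (rank 8), PNPase (rank 9) and larp (rank 17). The Polycomb group gene ph-p had the peak of rank 12 and the adaptor gene Shc that of rank 13. The remainder lay nearest to CG11050, CG4004, Art3, CG13323, CG1888, Pdrg1, CG9147, Tcs5 and CenG1A, with CG4004 and CG13323 at 5119 and 11912 bp from their TSS. Several of the 20 peaks, among them those at Chro, mRpL41, PNPase and Shc, also lay within 1000 bp of a TSS of a second gene. The gene named for such a peak is only the nearest.

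Several long genes carried many summits. CG1677 and kirre, a cell adhesion gene of myoblast fusion, held 11 each, kirre over 394 kb, for which its length predicts 9.19. CHES-1-like held 10 over 27.0 kb where length predicts 0.674, and sbb, the gene scribbler, held 10 where it predicts 1.88. The hemocyte regulator ush held 9, and Ptp61F, Raf, the kinase of the Ras pathway, and shn, the transcription factor schnurri of Dpp signalling, held 8 each. CG14434, Hr4 and simj held 7 each. These counts had no test.

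Gene lists addressed whether promoters of tendon, muscle or other embryonic genes were bound. In all, 2631 of 13945 protein-coding genes (18.9%) were bound. Of the tendon and muscle attachment list 4 of 16 members were bound (25%, interval 10.2 to 49.5%, odds ratio 1.55, adjusted exact p = 0.877): how, an RNA-binding protein of tendon maturation, with the peak of rank 112, the integrin genes if (rank 1492) and mys (rank 1943), and the cytoskeletal linker shot (rank 1644). Integrins and basement membrane had 5 of 18 bound (adjusted exact p = 0.764), among them Ilk (rank 376) and rhea (rank 1250), both adhesion adaptors, and parvin (rank 1497). The parvin peak ranked only 22732 in replicate 2. The integrin genes if and mys belong to both lists, so results for these lists are not independent. When each summit was given to the gene with the nearest TSS, both lists were called, with odds ratios of 4.80 (adjusted exact p = 0.0103) and 4.80 (adjusted p = 0.00695). That assignment gives more DNA to genes far from their neighbours and was not corrected for it. Under the 1000 bp promoter rule the odds ratio was 0.933 for tendon and 1.07 for integrins against lists matched on gene structure (adjusted permutation p = 1 for each). The nearest-TSS assignment itself was not set against matched lists. With replicate 2 alone 3 of the 18 integrin list members were bound (odds ratio 1.02), and with replicate 1 alone 7 (odds ratio 2.85).

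Ribosomal protein genes were bound more often than other genes, with 48 of 92 members (52.2%, interval 42.1 to 62.1%) against 18.6% of others, an odds ratio of 4.75 (adjusted exact p = 1.26e-11). Their strongest promoter peaks were at RpS27 (rank 96), RpL7 (rank 137), RpS20 (rank 141) and RpL34b (rank 163). Housekeeping and heat shock genes had 12 of 17 bound (odds ratio 9.81, adjusted exact p = 4.53e-05), with Gapdh2, a glycolytic enzyme (rank 199), Act5C, a cytoplasmic actin (rank 235), RpL32 (rank 515), also in the ribosomal list, and the chaperone Hsp83 (rank 601). Both lists were fixed as controls for signal at highly transcribed genes. The ribosomal odds ratio was 2.94 with replicate 2 alone and 6.57 with replicate 1 alone, and the housekeeping one ran from 5.75 with matched lists to 15.0 for the 1551 strongest peaks.

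The EGFR pathway list had 8 of 16 members bound (50%, interval 28.0 to 72.0%, odds ratio 4.31, adjusted exact p = 0.0304). They included the ligand genes spi (rank 126) and Krn (rank 857), the repressor aop (rank 656) and Ras85D (rank 689). The call was lost for the 1551 strongest peaks (odds ratio 4.04, adjusted exact p = 0.136), within 500 bp (odds ratio 3.13, adjusted exact p = 0.173) and against lists matched on gene structure (odds ratio 3.06, adjusted permutation p = 0.141). The odds ratio was 7.31 with replicate 2 alone and 10.1 by the nearest TSS.

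Segmentation and Hox genes, the patterning regulators of the early embryo, had 0 of 24 promoters bound (interval 0 to 13.8%, odds ratio 0.0876, adjusted exact p = 0.0707), which did not pass. It did against lists matched on gene structure (odds ratio 0.0628, adjusted permutation p = 0.0165), and by the nearest TSS the odds ratio was 1.35. The Notch pathway had 5 of 15 bound, with numb (rank 549), Nct (rank 779), mam (rank 2269) and neur (rank 2655), and 3 of 15 with replicate 2 alone (odds ratio 1.26 against 2.25). The E(spl) and Bearded complexes had 3 of 15, E(spl)m3-HLH (rank 755), E(spl)m7-HLH (rank 947) and E(spl)mdelta-HLH (rank 2046). Proneural and neurogenic bHLH genes had 2 of 14, da (rank 1737) and emc (rank 3024). In replicate 2 the E(spl)m7-HLH and E(spl)mdelta-HLH peaks ranked only 10238 and 21471, and the emc peak had no summit within 100 bp. Neither these lists nor the lists below passed the test.

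Muscle lists stood near the level of all genes in the main setting. For somatic muscle the odds ratio ran from 0.611 with gene bodies against lists matched on length to 2.81 by the nearest TSS. For muscle structural proteins it ran from 0.401 against lists matched on gene structure to 1.70 by the nearest TSS. None of these values was called. Somatic muscle identity and fusion had 4 of 22 bound, with mbc (rank 280), org-1 (rank 871), rols (rank 1353) and Poxm (rank 2002), and muscle structural proteins 3 of 20, Msp300 (rank 107), sls, the titin-like protein (rank 226), and TpnC47D (rank 2733). Wing and vein patterning had 2 of 18, among them bs (rank 2289). Cell type markers gave sty and pyd among 12 trachea genes, bgcn and nanos among 13 germline genes, ush among 12 hemocyte genes, fkh among 13 fat body and gut genes and CrebA among 16 epidermis and cuticle genes. The CrebA peak had no replicate 2 summit within 100 bp. The chordotonal and sense organ list had elav among 17 and the neuroblast list brat among 15.

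**Figure D3:**
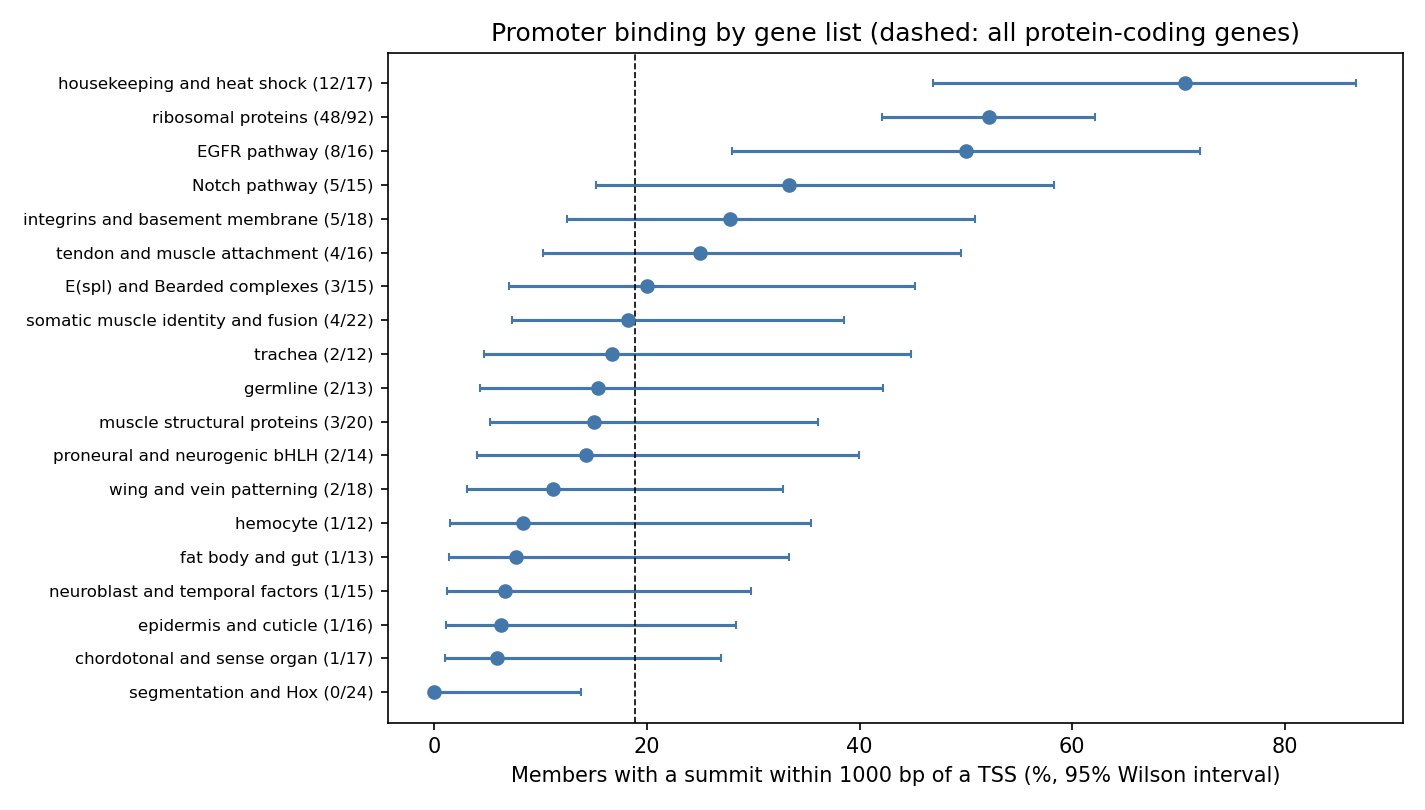
Share of each list's members with an optimal IDR summit within 1000 bp of a TSS (horizontal axis, points with 95% Wilson intervals, counts in parentheses), with the 18.9% of all protein-coding genes dashed. Only the housekeeping, ribosomal protein and EGFR lists have intervals wholly above the dashed line, and the segmentation and Hox list stands at 0 of 24.

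At tx itself (FBgn0288888, 3R from 26440778 to 26448991) no optimal IDR summit lay in the gene or within 1000 bp. The nearest was on 3R at 26452693 (rank 2341), 3701 bp beyond the gene and 159 bp from the TSS of CG5447. The relaxed lists held 9 summits there in replicate 1, with a best rank of 2450, and 7 in replicate 2, with a best rank of 2783. Of 829 genes of like length 7.36% and 5.67% held at least as many, and the medians were 4 and 3. The tagged copy and the endogenous gene cannot be separated by sequence here.

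Because bHLH proteins bind CANNTG (the E-box), summits were compared with their flanks. Any CANNTG stood at 1179 summits (38.0%, interval 36.3 to 39.7%) against 41.4% of flank windows, a ratio of 0.919 (adjusted exact p = 0.0456). Among the classes CACCTG was rarer at summits, at 3.16% against 4.88% (adjusted exact p = 0.00231), as was CACATG, at 3.77% against 5.19% (adjusted p = 0.0456). The other 8 classes did not pass, among them CAGCTG, at 4.90% against 4.95%. The call for any CANNTG was lost with replicate 1 alone (adjusted exact p = 0.0723), at 100 bp (adjusted p = 0.282), with controls 1000 bp away (adjusted p = 0.0711) and at distal summits (adjusted p = 1). That for CACATG was lost with replicate 1 or 2 alone (adjusted exact p = 0.0723 and 0.279), for the 1551 strongest peaks (0.0574), at 100 bp (0.22) and with controls 1000 bp away (0.0711). That for CACCTG was lost at 25 bp (ratio 0.642 against 0.647 in the main setting, adjusted exact p = 0.491) and at distal summits (ratio 0.907, adjusted p = 0.617). Against dinucleotide-shuffled summit windows CACATG stayed rarer, with a ratio of 0.709 (adjusted exact p = 0.0127), whereas CACCTG turned to 1.20 without a call (adjusted p = 0.684) and any CANNTG to 1.13 (adjusted exact p = 0.0022). CAGCTG and CATATG gained calls there, with ratios of 3.01 (adjusted exact p = 3.6e-14) and 1.53 (adjusted p = 0.0187). Flank windows were not set against their own shuffles, so an excess over shuffles need not be particular to summits. CAACTG was called rarer at 25 bp (adjusted exact p = 0.0472), with controls 1000 bp away (adjusted p = 0.025) and with replicate 2 alone (adjusted p = 0.00858), and CAAGTG at 25 bp (adjusted p = 0.0472). Mean GC content was 36.2% at summits (SD 8.71) and 44.0% in flanks (SD 10.4).

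Of motifs of other factors, TATCGATA, the site of the replication-related factor DREF, stood at 82 summits (2.64%) against 0.29% of flanks, a 9.11-fold excess (adjusted exact p = 9.91e-14). The ratio was 5.8 for the 1551 strongest peaks and 16.4 against shuffled windows. YTAWWWWTAR, the Mef2 site, was 1.86-fold more frequent (adjusted exact p = 9.18e-07). GAGAG, bound by GAGA factor, was rarer (ratio 0.699, adjusted exact p = 9.18e-07), as was the CA repeat CACACA (ratio 0.595, adjusted p = 1.92e-10). The sites of Zelda (CAGGTA), grainy head (AACCGGTT) and stripe (GCGTGGGCG) did not pass. At 100 bp GCGTGGGCG was called rarer (ratio 0.261, adjusted exact p = 0.00774). At the 1088 summits over 1000 bp from a TSS TATCGATA stood at 1 (ratio 0.5, adjusted exact p = 1), and the calls for YTAWWWWTAR (ratio 1.04, adjusted p = 1) and GAGAG (ratio 0.818, adjusted p = 0.729) were lost. Against shuffled windows the YTAWWWWTAR call was also lost (ratio 1.26, adjusted exact p = 0.0589), CACACA turned to 1.23 without a call (adjusted p = 0.0587), and GAGAG turned to 1.41 (adjusted exact p = 0.000185). In the 6-mer scan 458 words were more frequent at summits, with a mean GC of 26.7%, and 752 were rarer, with 67.0%. The leading word was TTAAAA (29.7% against 13.5%, adjusted exact p = 1.9e-47).

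Strong and weak peaks differed in position and not detectably in E-boxes. Among the 620 strongest peaks 72.7% were at promoters, and among the 620 weakest of the set 62.6% (Fisher's exact test, odds ratio 1.59, adjusted p = 0.000491). Any CANNTG stood at 37.3% and 39.5% (adjusted exact p = 0.672), and CATATG, the class with the highest ratio to flanks, at 3.87% and 3.71% (adjusted p = 1). TATCGATA, tested after the data were seen, stood at 1.13% of the strongest and 2.90% of the weakest (unadjusted exact p = 0.0412).

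**Figure D4:**
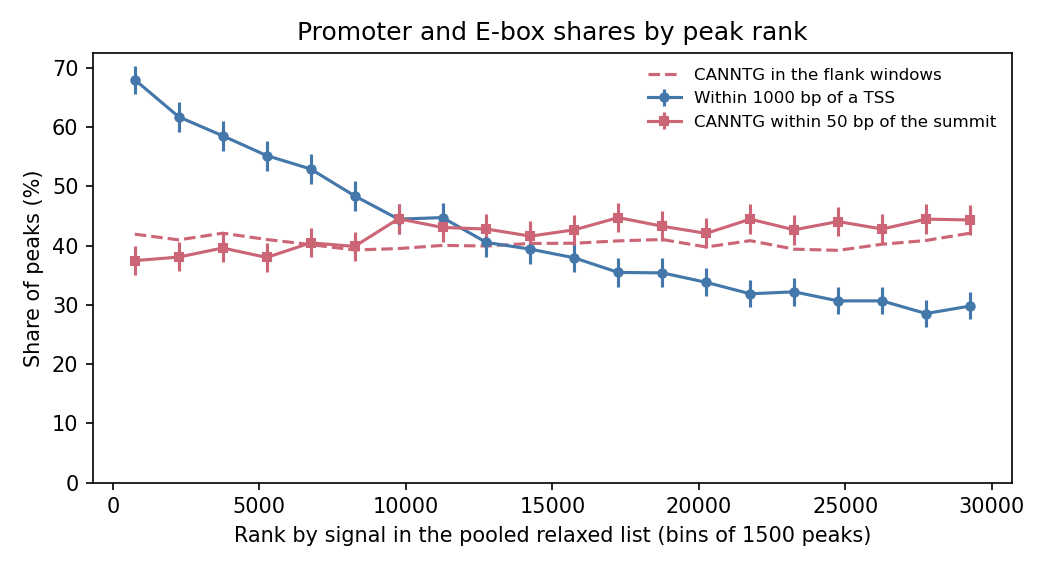
Share of peaks within 1000 bp of a TSS (blue) and with CANNTG within 50 bp of the summit (red squares) or in the flank windows (dashed), in bins of 1500 peaks by signal rank in the pooled relaxed list, with 95% Wilson intervals. The promoter share is 68% in the first bin and 29.8% in the last, and the CANNTG share at summits is 37.5% and 44.3%.

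On dm3 the optimal IDR set held 2997 peaks covering 1059 kb, with 731 on 3R, 580 on 3L, 568 on 2L, 566 on 2R, 540 on X and 12 on chromosome 4. The dm6 set had 749, 601, 585, 594, 561 and 12 on these arms. Relaxed lists covered 11539 kb in replicate 1 and 11042 kb in replicate 2 on dm3, and 11637 and 10945 kb on dm6.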

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

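The test of peak rank below was set before its result was seen. Peaks on heterochromatin and unplaced contigs appeared in the dm3 relaxed lists, which no comparison uses. There were 348 in replicate 2, 26 in replicate 1 and 46 in the pooled list, each above the 3 counts that a count of 0 allows. The optimal IDR sets and the dm6 lists held 0 on such contigs. As dm3 coordinates were not converted, whether the dm6 arms include these sites was not tested. Most of the replicate 2 peaks were on 3LHet (119), 2RHet (92) and 3RHet (81).

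Background at the weak end of the lists was set against these peaks. It required that none stood among the top 2997 of replicate 2, and 2 did (0.0667%, interval 0.0183 to 0.243%), the first at rank 2041, while they made up 1.16% of the whole list with a median rank of 20028.5. The interval lay below the share of the whole list, so these peaks were rarer among the strongest of replicate 2. As 2 peaks stood there, the requirement of none was still not met, and that explanation stays open. A difference in alignment or depth between the replicates was not tested, and no biological explanation was tested, since the design has 1 group.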

How the results depend on the processing

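Alternatives for the other motifs and 6-mers, and the arms without Y, were chosen after the data were seen. In all, 310 comparisons with alternatives kept direction and side of the threshold, 22 lost a call, 10 gained one, 54 turned direction, most of them without a call in either setting, and 5 other values moved. The cause was not tested unless stated. The planned top 3102 of the pooled list is the optimal IDR set itself and gave no separate value. No paired analysis was possible because there is 1 group. Depth is unknown, and replicate 1 or 2 alone was ranked to the same number of peaks. Promoter, intron, intergenic, coding exon and 3′ UTR results, the ribosomal and housekeeping lists and the replicate overlap kept their calls in every alternative run, the overlap ranging from 51.1% to 72.1%. With summits within 50 bp rho was 0.70.

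With a TSS distance of 500 bp the ratio of 5′ UTR summits was 0.649, and the odds ratios were 3.13 for EGFR, 1.01 for proneural, 0.934 for E(spl), 0.658 for trachea and 1.10 for germline. With 2000 bp they were 0.342 for 5′ UTR, 0.799 for trachea and 1.12 for germline. By the nearest TSS, tendon and integrins rose to 4.80 each, and odds ratios were 1.70 for muscle structure, 1.46 for proneural, 1.35 for segmentation and Hox, 2.49 for wing, 1.24 for epidermis, 1.14 for hemocyte and 1.04 for fat body and gut. With gene bodies against lists matched on length they were 0.611 for somatic muscle and 0.377 for trachea. Against lists matched on gene structure they were 0.933 for tendon, 0.629 for somatic muscle, 3.06 for EGFR, 0.0628 for segmentation and Hox and 0.661 for trachea. For the 1551 strongest peaks the TATCGATA ratio was 5.8, and odds ratios were 1.14 for muscle structure, 4.04 for EGFR, 1.10 for hemocyte, 1.83 for germline and 1.01 for fat body and gut, the arm ratios were 1.10 for 2L and 0.597 for chromosome 4 (fewer peaks), CACATG was 0.655 and the CANNTG odds ratio of strong against weak peaks 1.01. Without Y, 2L was 1.07.

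Among motif ratios, 25 bp either side gave 1.05 for CAAATG, 0.697 for CAACTG, 0.792 for CAAGTG, 1.05 for CAATTG, 0.642 for CACCTG and 0.991 for CATATG. With 100 bp they were 0.979 for any CANNTG, 1.04 for CAATTG, 0.833 for CACATG, 1.11 for CAGCTG and 0.261 for GCGTGGGCG. With controls 1000 bp away they were 0.909 for any CANNTG, 0.723 for CAACTG, 1.03 for CAATTG, 0.767 for CACATG and 1.43 for AACCGGTT. Against shuffles, which share the summits' base composition, they were 1.13 for any CANNTG, 1.03 for CAAATG, 1.21 for CAACTG, 1.24 for CAAGTG, 1.20 for CACCTG, 1.10 for CACGTG, 1.26 for CAGATG, 3.01 for CAGCTG, 1.53 for CATATG, 1.41 for GAGAG, 16.4 for TATCGATA, 1.67 for AACCGGTT, 2 for GCGTGGGCG, 1.26 for YTAWWWWTAR and 1.23 for CACACA, with 151 6-mers enriched and 187 depleted. At distal summits, which are fewer, they were 0.928 for any CANNTG, 1.05 for CAAGTG, 0.907 for CACCTG, 0.818 for GAGAG, 1.27 for CAGGTA, 0.5 for TATCGATA and 1.04 for YTAWWWWTAR, with 225 6-mers enriched and 312 depleted. Calls were gained for CAACTG and CAAGTG at 25 bp, for CAACTG with controls 1000 bp away, and for CAGCTG and CATATG against shuffles. The CACCTG call was lost at 25 bp and at distal summits, and the GAGAG call at distal summits.

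With 1 replicate alone calls were gained for CAACTG and X (replicate 2) and lost for any CANNTG (replicate 1) and CACATG (either). The motif ratios ran from 0.901 to 1.02 for CAAATG, 0.673 to 0.812 for CAACTG, 0.756 to 0.822 for CACATG, 0.811 to 1.10 for CAGATG, 0.902 to 1.04 for CAGCTG and 0.889 to 0.926 for any CANNTG. Arm ratios ran from 0.984 to 1.03 for 2R and 1.03 to 1.12 for X. Odds ratios ran from 1.45 to 1.5 for germline, 0.588 to 1.04 for hemocyte, 1.02 to 2.85 for integrins, 1.26 to 2.29 for Notch, 0.0918 to 0.278 for segmentation and Hox, 0.782 to 1.78 for somatic muscle and 0.921 to 1.27 for CATATG in strong against weak peaks. For proneural genes they ran from 0.501 to 0.872, for chordotonal genes from 0.396 to 0.727 and for epidermis from 0.136 to 0.422.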

Other observations

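The gene families, core promoter motifs and lower-ranked peaks in these paragraphs were chosen after the results were seen, and the expected outcomes of the tests on E-boxes and on gene structure and single replicates were also set down only after those results were seen. Among 68 families of at least 10 genes sharing a symbol prefix, 4 were bound more often and 9 less often than other genes (Fisher's exact test, adjusted over the families). Peroxisome biogenesis genes (Pex) had 8 of 15 bound (odds ratio 4.88, adjusted exact p = 0.0178). RpL and RpS, which the ribosomal list holds, were also higher. Histone genes (His) had 1.74% of members bound (adjusted exact p = 1.63e-06), odorant receptors (Or) 0 of 59 and gustatory receptors (Gr) 0 of 60 (adjusted p = 9.04e-05 for each), cytochromes P450 (Cyp) 2 of 85 (adjusted p = 9.78e-05) and cuticle proteins (Cpr) 1 of 70 (adjusted p = 0.000102). Ir, Obp, Ugt and Osi were also lower. Histone and other clustered genes can share a peak or its absence, so members are not independent. How well reads map to gene copies of similar sequence was not examined.

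Core promoter motifs within 100 bp of any TSS of a gene differed in frequency between bound and unbound genes. More TSSs give a gene more chances both to be bound and to hold a motif, and TSS number was not matched here. Ohler motif 7 stood at 18.4% of 2631 bound and 6.74% of 11314 unbound genes (odds ratio 3.13, adjusted exact p = 6.26e-67), the DRE at 21.8% and 13.4% (odds ratio 1.80, adjusted p = 8.04e-25), and Ohler motif 5, which contains CAGCTG, at 6.39% and 3.04% (odds ratio 2.18, adjusted p = 3.11e-14). Ohler motif 1 stood at 6.23% and 3.90% (odds ratio 1.64, adjusted exact p = 4.78e-07). The TATA box was rarer at bound genes, at 5.13% and 10.1% (odds ratio 0.483, adjusted exact p = 9.73e-17). Ohler motif 6 did not pass (adjusted exact p = 0.0962). Against shuffled windows the leading 6-mers at summits were TATCGA (9.83% against 3.24%), ATCGAT and CGATAG. AAATAT ranked 4. CAGTGG, ACAGTG, CACTGA and ACACTG, which share CAGTG or its reverse complement, ranked 5 to 8, and CAGCTG ranked 9.

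Peaks ranked below the optimal IDR set had some E-box classes more often than their flanks and others less often. In the pooled list any CANNTG stood at 42.5% of 26898 summits and 40.4% of flanks (ratio 1.05, adjusted exact p = 3.59e-06). Among the classes CAGCTG (ratio 1.35, adjusted exact p = 4.11e-17), CACCTG (1.27, adjusted p = 5.44e-08), CACATG (1.14, adjusted p = 0.0096) and CAACTG (1.08, adjusted p = 0.0358) were more frequent. CAAATG (ratio 0.933) and CAATTG (ratio 0.886) were rarer than in the flanks (adjusted exact p = 0.0121 for each), and CATATG did not differ detectably (ratio 0.999). In each replicate's own lower-ranked peaks any CANNTG, CAGCTG and CACCTG kept their calls. CACATG lost its call in both (adjusted exact p = 0.0582 in replicate 1 and 0.363 in replicate 2). CAAATG lost it in replicate 1 (adjusted exact p = 0.906), and CAACTG (0.133) and CAATTG (0.201) in replicate 2. CAGATG gained a call as more frequent in both (adjusted exact p = 0.011 and 0.0321), and CAAGTG in replicate 2 (0.0261). The mean GC of these summits was 45.0% in the pooled list, against 42.2% in the flanks, the opposite order to the optimal IDR peaks, and base composition was not removed from this comparison.

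The absence of a CANNTG excess at optimal IDR summits was weighed against 3 explanations. Dilution by weak peaks of an excess over flanks is argued against, since in the 620 strongest the ratio to flanks was 0.887 (bootstrap interval 0.786 to 0.998). Flanks of the whole set were richer in GC, and the 620 strongest were not compared with shuffles. Whether they hold an excess over their own base composition therefore stays open. An excess hidden by promoter peaks was not seen at the 1088 distal summits, where the ratio was 0.928, but its interval (0.846 to 1.03) includes 1, so this stays open. Base composition could not be decided: against shuffles of the same windows the ratio was 1.13 (adjusted exact p = 0.0022), but flanks were not set against their own shuffles. CAGCTG, with a ratio of 3.01 against shuffles, stood at 4.90% of summits and 4.95% of flanks. An excess over shuffles therefore need not be particular to summits. A role of tx at sites without an E-box was not tested.

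The frequent binding of ribosomal protein promoters was weighed likewise. Gene structure is argued against as the whole cause, as the odds ratio was 4.19 against lists matched on TSS number and gene length (adjusted permutation p = 0.0038), and so is a single replicate, as the lower odds ratio of the replicates alone was 2.94 (adjusted exact p = 3.8e-05). Signal at highly transcribed genes in any immunoprecipitate cannot be told apart from binding of tx, because 0 immunoprecipitates without the tagged protein were analysed here. No biological explanation was tested, since the design has 1 group.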
